A study of Mus musculus with 10 samples.

How the data were processed

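Transcripts were measured in 10 sections of mouse skin with Xenium Prime, an in situ assay in which probes bound to RNA inside a tissue section are read by repeated imaging and each decoded transcript is assigned to a segmented cell. The tissue was fixed in formalin and embedded in paraffin, per the labels' protocols. The authors deposited, for each section, a matrix of whole-number transcript counts per feature and segmented cell, and these counts were not normalized. Scanpy is named in the submitters' processing notes without a version or a role. The segmentation method, the decoding threshold and the software versions are not given in the sources used here. The features were 5106 genes, 40 negative control probes, 609 negative control codewords, 21 genomic controls, 7674 unassigned codewords and 8 deprecated codewords. Only the genes entered library sizes and tests, and the remaining features held between 0.0416% and 0.0626% of the transcripts of a section.

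Groups were taken from the sample titles. The genotype field names the floxed gene as deleted in both control skin sections and in the control wound, although their titles call them controls without recombination, and the titles were followed. The labels do not say whether replicate sections came from separate animals, so p-values measure the spread between these sections. Xist, which is expressed from the inactive X chromosome of females, differed within the pairs of Nedd8 knockout wounds (0.435 and 478 CPM) and Nedd8 Nrf2 knockout skin (5.10 and 471 CPM), so each of these pairs came from separate animals. For the control skin and Sumo2 knockout pairs, where Xist was at most 4.02 CPM, the spread may be technical. The counts of the control skin pair differed far beyond sampling noise, with a chi-square of 74.8 per degree of freedom, so no section was treated as a copy of another. The sections lay on 2 slides, 5 on each, with control skin 1, both Sumo2 knockout sections, the control wound and Nedd8 knockout wound 1 on the first slide.

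Cells with fewer than 20 transcripts were left out, which removed between 4.87% and 19.8% of the cells of a section. No doublet caller was run, because a segmented cell in a tissue section can take transcripts from its neighbours, and mixed cells therefore stay in the sums. Up to 6000 cells per section were scaled to the median depth, log-transformed and reduced to 40 principal components, and a graph of 15 neighbours was clustered with the Leiden method (leidenalg 0.10.2, python-igraph 0.11.9, resolution 1, seed 1). Members of the fixed gene lists named further on were left out of the clustering, except the basal, differentiation, scar matrix, bystander and epithelial-mesenchymal lists, which hold cell type markers. All other cells took the majority cluster of their 15 nearest sampled cells (scikit-learn 1.9.0). The 33 clusters were named from marker lists fixed before the data were examined, as keratinocyte-like, hair follicle-like, sebocyte-like, fibroblast-like, endothelial-like, macrophage-like, neutrophil-like and so on, and clusters 3, 6, 27 and 29 stayed unnamed. The unnamed clusters held a mean of 15.5% of kept cells in control skin and 17.7% in Sumo2 knockout skin. They held 5.95% and 7.54% in Nedd8 Nrf2 knockout skin against 17.0% in the Nrf2-null control, and 3.14% and 14.8% in the Nedd8 knockout wounds against 13.5% in the control wound. Class names rest on transcripts alone and no image was used.

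Raw counts were summed per section over all kept cells (whole section) and over keratinocyte-like, fibroblast-like and macrophage-like cells. The sums were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) after TMM scaling and filterByExpr filtering, with a robust fit of all 10 sections in 6 groups, so that the spread was estimated with 4 residual degrees of freedom. The control wound and the Nrf2-null control were single sections, and each was assumed to vary like the other groups. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p of 0.05. The common biological coefficient of variation was 0.300 in keratinocyte-like cells, 0.338 in whole sections, 0.296 in fibroblast-like cells and 0.264 in macrophage-like cells. Levels are given as CPM, the counts of a class in a section divided by its TMM-scaled library size. Fixed gene lists were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. Class shares carry exact 95% binomial intervals, which cover counting error only. Where 1 to 3 counts stood on one side, a ratio is given with its counting interval, and where a group had 0 counts, the fold is a lower bound against 3 counts over the group.

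The 6 comparisons were Sumo2 knockout against control skin, Nedd8 knockout wound against control wound, Nedd8 Nrf2 knockout skin against Nrf2-null control skin, control wound against control skin, Nrf2-null control against control skin, and the Sumo2 effect minus the Nedd8 effect on the Nrf2-null background. The 19 lists fixed before the data were examined covered NRF2 targets, interferon response, p53 targets, cell cycle, basal keratinocyte, keratinocyte differentiation, stress and wound keratinocyte, inflammatory cytokines and chemokines, NF-kB feedback and targets, hypoxia and HIF targets, Wnt pathway targets, unfolded protein and ATF4 response, heat shock and proteasome, ubiquitin-like conjugation machinery, cell death, DNA damage and checkpoint, myofibroblast and scar matrix, melanocyte and immune bystander genes, and epithelial-mesenchymal genes. Genes were named by a rule fixed at the same time. Among called genes with an average log2 CPM of at least 4 whose treated sections all lay on one side of all control sections, the 10 largest changes each way were named in keratinocyte-like cells of the Sumo2, Nedd8 wound and Nedd8 Nrf2 comparisons, and the 4 largest each way elsewhere. Where none passed, the 5 genes with the smallest p are given as values. The targeted genes and up to 4 members of each list with the smallest p were added. Some genes that this rule takes are not reported here.

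Tested on simulated data with 200 changed genes among 3803, the procedure recovered 5.97%, 61.2% and 86.4% of genes changed 2-fold, 4-fold and 8-fold in keratinocyte-like cells of the Nedd8 Nrf2 comparison, with 4 false calls among 106. For the Sumo2 comparison it recovered 14.9%, 62.7% and 80.3%, with 7 false calls among 112. For the Nedd8 wound comparison it recovered 1.49%, 47.8% and 74.2%, with 9 false calls among 91. Simulated genes varied independently around a shared abundance profile, without differences in cluster mix or doubtful labels. These rates may therefore not hold for the real sections. The alternatives planned before the data were examined were library-size scaling without TMM, DESeq2 1.42.0, no filter on low counts, only the groups compared, slide as a block, the replicate number as a block, only the first slide, at least 50 transcripts per cell, Leiden resolution 2, clustering on all panel genes, an estimated correlation, and leaving out each replicate. Added after seeing the data were leaving out the sections labelled control skin 1 and Nedd8 knockout wound 2 together, leaving out each of them from comparisons they are not part of, Xist above 100 CPM as a covariate, and pooling the unnamed follicle-type clusters with the keratinocyte-like class. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.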

Results

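NEDD8 and SUMO2 are small ubiquitin-like proteins that are joined to other proteins. The knockout mice were designed to lose Nedd8 or Sumo2 in cells that express the keratin 14 promoter, which is active in basal epidermis and hair follicles. Floxed C57/Bl6 mice with or without the tamoxifen-driven K14-Cre recombinase gave 2 control skin sections, 2 Sumo2 knockout skin sections, 1 control wound, 2 Nedd8 knockout wounds, 2 skin sections lacking Nedd8 on an Nrf2-null background (Nedd8 Nrf2 knockout), and 1 Nrf2-null control skin section. Tamoxifen was given for 5 days, or for 3 days in wounded mice. The labels give harvest as 3 days after recombination for every section, and also as 14 days after wounding for the wounds, without saying how these times relate. Each section held between 4554726 and 20809710 gene transcripts, lowest in the control wound and highest in the section labelled Nedd8 knockout wound 1. Median depth was 62 transcripts per cell in the control wound, 79 in the section labelled Nedd8 knockout wound 1, and between 120 and 287 in the other sections. After filtering, kept cells numbered 21594 in the section labelled control skin 1, 36309 in control skin 2, and 38349 and 37086 in Sumo2 knockout skin. They numbered 36340 in the control wound, 104956 and 22309 in the Nedd8 knockout wounds, 30275 and 27148 in Nedd8 Nrf2 knockout skin, and 53035 in the Nrf2-null control. Negative control probes averaged between 0.5 and 3.525 counts per section, against 892 to 4076 counts per gene.

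The targeted genes were read first in keratinocyte-like cells, since they check the labels. Nfe2l2, which encodes the antioxidant regulator NRF2, had 0, 1 and 1 counts in the 3 Nrf2-null sections and between 258 and 596 CPM in the other 7. Nedd8 stood at 175 and 171 CPM in Nedd8 Nrf2 knockout skin, against 821 CPM in the Nrf2-null control, and fell by 2.25 on the log2 scale (SE 0.62, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0459). That Nedd8 call was lost without knockout 1 (adjusted p = 0.202), without knockout 2 (0.164), without the section labelled control skin 1 (0.0795) and with no filter on low counts (0.0561), in the same edgeR test. In the sections labelled Nedd8 knockout wound, Nedd8 was 159 CPM in replicate 2 but 617 CPM in replicate 1, against 672 CPM in the control wound, and the log2 difference of -0.79 was not called (SE 0.63, edgeR adjusted p = 0.502). Without the section labelled Nedd8 knockout wound 1 the Nedd8 difference was -2.08 (edgeR adjusted p = 0.00557), and without the section labelled wound 2 it was -0.16 (edgeR adjusted p = 0.781). Sumo2 was 221 and 142 CPM in Sumo2 knockout skin and 1168 CPM in control skin 2, but only 158 CPM (266 counts) in the section labelled control skin 1. The Sumo2 log2 difference was -1.87 (SE 0.80, edgeR adjusted p = 0.824), -2.67 without the section labelled control skin 1 (edgeR adjusted p = 0.113) and 0.20 without control skin 2. The positions of the probes are not given in the sources used here, and a probe outside the deleted part of a gene would check nothing. Groups were kept as labelled.

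**Figure D1:**
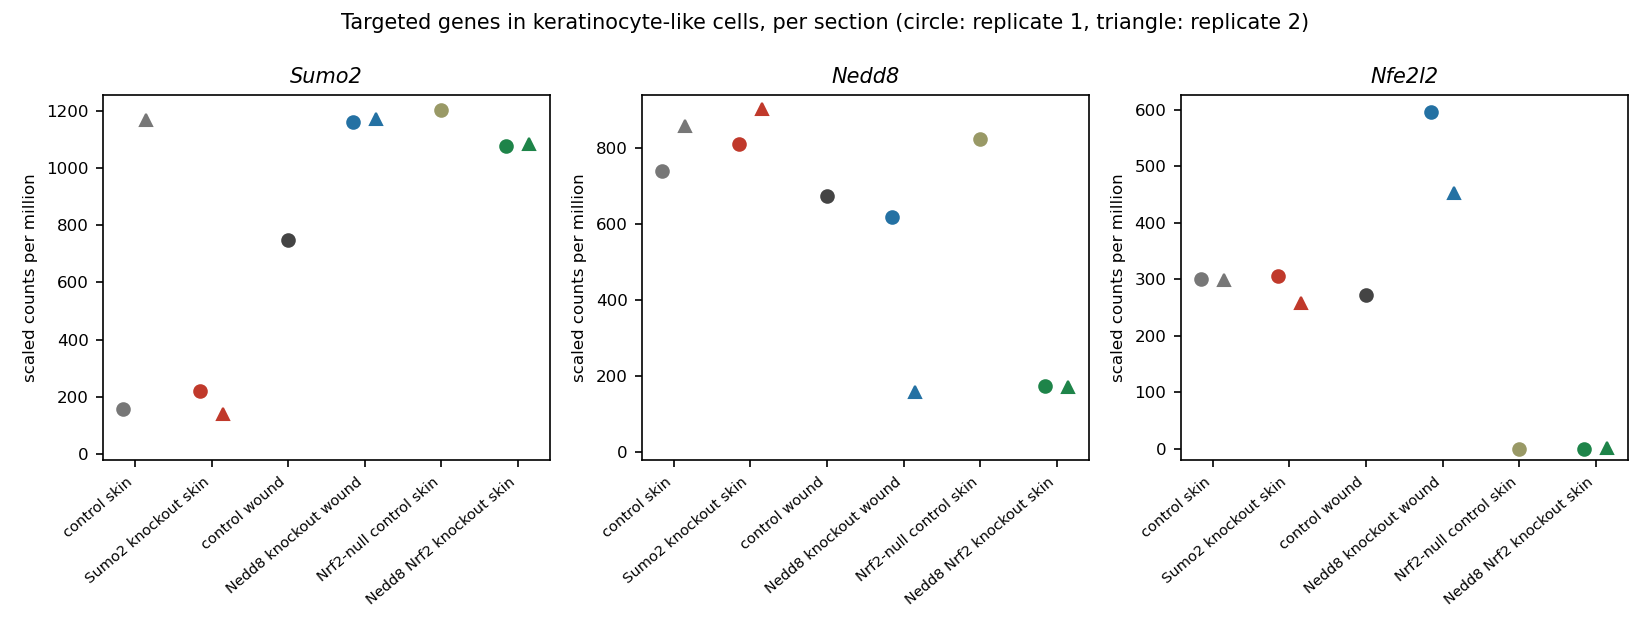
TMM-scaled CPM of Sumo2, Nedd8 and Nfe2l2 in keratinocyte-like cells, one point per section on a linear axis, with circles for replicate 1 and triangles for replicate 2. The section labelled control skin 1 had 158 CPM of Sumo2, the section labelled Nedd8 knockout wound 1 had 617 CPM of Nedd8, and Nfe2l2 was near 0 in the 3 Nrf2-null sections.

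Nedd8 Nrf2 knockout skin was set against Nrf2-null control skin to ask what Nedd8 loss does in epidermis that lacks NRF2. Its keratinocyte-like cells had higher levels of stress and wound keratinocyte genes, with 15 of 27 called. Krt6a, a keratin of stressed epidermis, stood at 59305 and 50450 CPM against 549.9 CPM in the control (log2 change 6.64, SE 1.25), and Il24, a cytokine of the IL-10 family, at 2175 and 1053 CPM against 5.9 CPM (8.08, SE 1.10). Among the genes that fell were the transcription factor Sox6, from 195 CPM to 3.3 and 7.0 CPM, and Clca3a2, from 1865 CPM to 38.0 and 55.8 CPM. With the edgeR quasi-likelihood test, 655 of 3803 genes were called after Benjamini-Hochberg adjustment, 277 higher and 378 lower, and 622 of them changed more than 2-fold. Most keratinocyte-like cells of the 2 knockout sections lay in clusters 11 and 20 (96.1% and 91.2%), which held 1.32% of the class in the control, so the values compare largely different clusters. Aldh1a3, Sprr2f and Cntn2 are among the 10 leading genes of cluster 11, and Il24 and Nppb among those of cluster 20. Il22ra2, Clca3a2, Slc24a3 and Gna14 are among those of cluster 9, which held 4687 control cells and 39 and 74 knockout cells. For 583 called genes that were expressed well enough, both knockout sections lay on one side of the control, an arrangement that chance gives 66.7% of the time. The largest increases besides Krt6a and Il24 were in the retinoic acid enzyme Aldh1a3 (8.49), the adhesion molecule Cntn2 (8.07, SE 0.95), the cornified envelope gene Sprr2f (7.87), the protease inhibitor Spink12 (7.26), the natriuretic peptide Nppb (7.25), the neuronal tubulin Tubb3 (7.22) and the hyaluronan-binding Cemip (6.56). Snai3, a Snail-family repressor, had 273 counts against 1, a ratio of 233 with a counting interval of 41.5 to 9251. The largest decreases were in the guidance molecule Sema3d (-6.20), the soluble IL-22 receptor Il22ra2 (-5.92), the procollagen protease Adamts14 (-5.74, SE 0.44), Clca3a2 (-5.31), Sox6 (-5.19, SE 0.49), the ion exchanger Slc24a3 (-5.00), the G protein subunit Gna14 (-4.92, SE 0.35), acetylcholinesterase Ache (-4.81), Bmp3 (-4.72) and the basement membrane collagen Col4a5 (-4.71). Benjamini-Hochberg adjusted p from edgeR for these 20 genes ran from 0.000532 for Gna14 to 0.0319 for Aldh1a3 and Sprr2f.

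**Figure D2:**
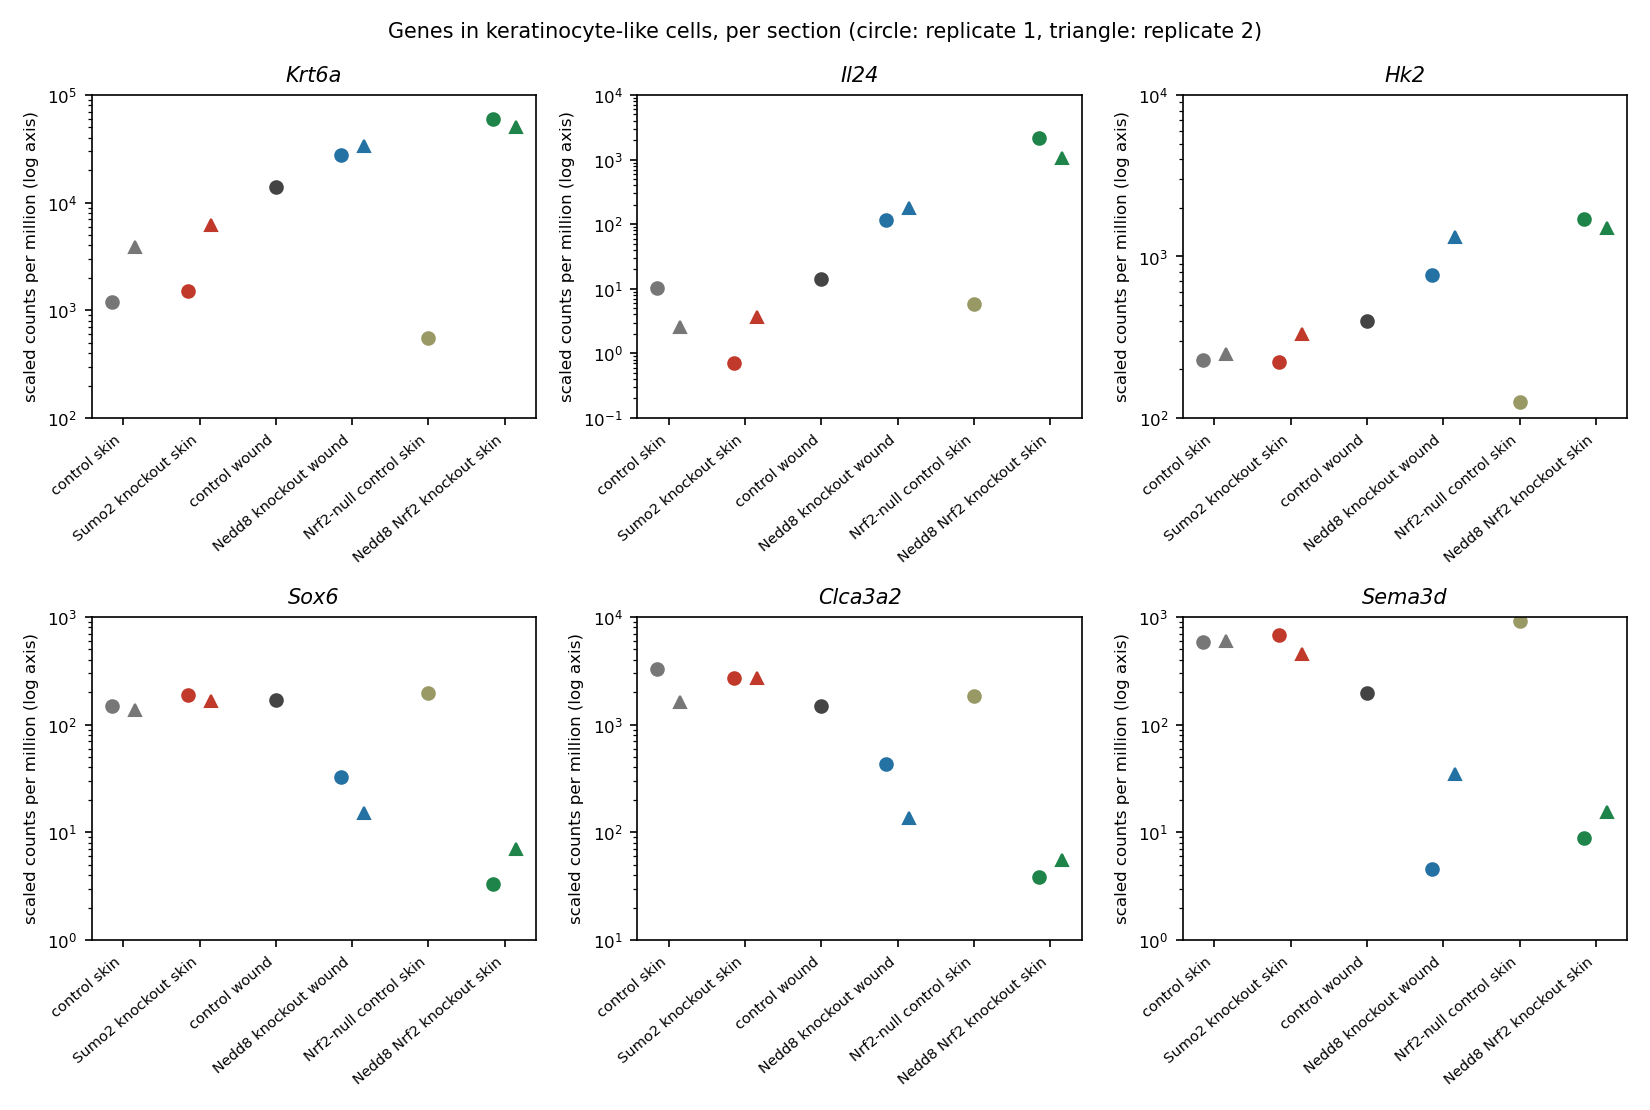
TMM-scaled CPM of Krt6a, Il24, Hk2, Sox6, Clca3a2 and Sema3d in keratinocyte-like cells, one point per section on a log axis, with circles for replicate 1 and triangles for replicate 2. Krt6a was 59305 CPM in Nedd8 Nrf2 knockout skin 1 and 549.9 CPM in the Nrf2-null control, and Sox6 was 3.3 and 195 CPM in the same sections.

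Those counts of genes rested on both knockout sections. Without Nedd8 Nrf2 knockout 1, 113 genes were called in keratinocyte-like cells and 12 of the 20 named genes remained, the lost ones being Aldh1a3, Cemip, Krt6a, Nppb, Sema3d, Snai3, Spink12 and Sprr2f. Without knockout 2, 245 genes were called and 15 named genes remained, without Aldh1a3, Nppb, Sema3d, Spink12 and Sprr2f. Aldh1a3 was also lost without the section labelled control skin 1, and Aldh1a3, Nppb and Sprr2f were lost with no filter on low counts. Xist as a covariate lost Aldh1a3 and Nppb, only the groups compared lost Nppb, and the pooled follicle-type clusters lost Snai3. Without the section labelled Nedd8 knockout wound 2, which enters only through the spread, 1226 genes were called. Scaling by library size alone moved the median of all genes by -0.41 and gave 966 calls, 210 higher and 756 lower.

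Grouped by the fixed lists, the stress and wound keratinocyte genes changed most in keratinocyte-like cells of Nedd8 Nrf2 knockout skin. Of 27 measured members 15 rose and none fell (21 rose when adjusted over the list alone), among them the EGF receptor ligands Tgfa (3.77, SE 0.36), Hbegf (5.98) and Areg (5.02) and the keratins Krt16 (4.65) and Krt17 (3.21). Camera gave an adjusted p = 1.03e-12, and adjusted p = 0.235 with an estimated correlation. Of 20 hypoxia and HIF targets 7 rose (10 adjusted over the list alone), including the glycolytic genes Hk2 (3.69, SE 0.46) and Eno1 (2.0) and the angiogenic factor Vegfa (1.87). Camera gave an adjusted p = 7.26e-05, and adjusted p = 0.408 with an estimated correlation. Of 37 inflammatory cytokines and chemokines 5 rose and 1 fell, the same numbers as when adjusted over the list alone. The neutrophil attractant Cxcl1 (4.44), Il1a (3.17), Il1b (4.35), the monocyte attractant Ccl2 (3.27) and Il33 (1.65) were higher and Csf1 (-1.67) was lower. Camera gave an adjusted p = 0.00204, and adjusted p = 0.722 with an estimated correlation. Transcripts of neighbouring immune cells were not excluded for these cytokines. Neutrophil-like cells made up 2.49% and 4.17% of kept cells against 0.447% in the control, and macrophage-like cells 35.1% and 30.5% against 12.5%. Of 33 myofibroblast and scar matrix genes 4 rose (4 adjusted over the list alone), namely Acta2 (2.31), Runx1 (2.40), Runx2 (3.03) and Inhba (4.70), with camera adjusted p = 0.000814, and adjusted p = 0.235 with an estimated correlation. Of 22 keratinocyte differentiation genes 5 rose, among them Ovol1 (1.85) and Klk7 (2.51), and the suprabasal keratin Krt10 fell (-3.78). The numbers were 6 and 1 when adjusted over the list alone, with camera adjusted p = 0.0484, and adjusted p = 0.708 with an estimated correlation. No list call in any comparison or compartment held with an estimated correlation.

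The other 14 lists were not called by camera in that comparison. Among 21 basal keratinocyte genes 6 fell, including Sox6, the receptor Fgfr2 (-3.13) and the hemidesmosome gene Dst (-1.51), and 3 rose, including the keratin Krt14 (1.66) and Itgb1 (1.31). The numbers were 8 and 4 when adjusted over the list alone and camera adjusted p = 0.0997. Of 19 p53 targets 5 rose and 2 fell (7 and 4 adjusted over the list alone), with Cdkn1a at 1.22, Plk2 at 3.41 and Fas at -2.03. Of 21 Wnt pathway targets 3 rose and 4 fell (4 and 5 adjusted over the list alone), with the feedback gene Axin2 at -2.17 and the ligand Wnt10b at -5.92. Of 38 cell death genes 1 rose and 5 fell, with the inhibitor of apoptosis Birc2 at -2.40 and Bcl2l1 at 1.12. Of 26 NF-kB feedback genes 1 rose and 4 fell, with Relb at -1.90 and Bcl3 at 2.06. Adjustment over the list alone gave the same numbers for both. Of 44 cell cycle genes Ccne1 (3.10) and Mybl2 (2.66) rose and Ttk (-1.94) fell, with 0 when adjusted over the list alone. Of 20 epithelial-mesenchymal genes Cdh3 (1.05) and Sox9 (3.94) rose, 1 when adjusted over the list alone. Of 14 unfolded protein and ATF4 response genes Cebpb (1.54) rose, 7 when adjusted over the list alone. In the ubiquitin-like conjugation list of 31 genes, Nedd8 and the SUMO ligase Pias3 (-1.98) fell, 1 of them when adjusted over the list alone. The checkpoint kinase Wee1 (-2.09) was the only call among 33 DNA damage genes, also when adjusted over the list alone. Irf1 (-1.49) was the only call among 28 interferon response genes, with 0 when adjusted over the list alone. None of 12 NRF2 targets and none of 14 heat shock and proteasome genes was called, either way, by edgeR. Of 20 melanocyte and immune bystander genes, the Langerhans cell gene Cd207 (-1.86) and the lymphocyte gene Nkg7 (-2.36) fell and Kit (4.34) and the macrophage gene Cd68 (1.72) rose, 3 and 2 when adjusted over the list alone. This list's median of -0.29 and mean of 0.32 differ in sign.

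Outside the epidermis, fibroblast-like and macrophage-like cells of Nedd8 Nrf2 knockout skin had higher levels of some cytokine genes and of Saa1. In fibroblast-like cells Cemip had 558 counts against 0, at least 127-fold higher, the acute-phase gene Saa1 had 1835 against 1 (ratio 1252, counting interval 224 to 49472), and the stromelysin Mmp10 had 329 against 2 (ratio 112, 30.8 to 931). The neutrophil attractant Cxcl5 rose by 8.04 on the log2 scale, and Gpm6a (-4.18), the growth factor receptor Fgfr4 (-3.27), Adcy1 (-2.91) and Syne1 (-2.33) fell. In macrophage-like cells Saa1 had 540 counts against 1 (ratio 156, counting interval 27.9 to 6187). The matrix protein Tnc (6.63), the growth factor Nrg1 (6.36) and the BMP antagonist Grem1 (5.45) rose in these cells, and the lipid receptor Cd36 (-2.76), the iron exporter Slc40a1 (-2.76), Ppl (-2.75) and Gpc3 (-2.36) fell. With edgeR, 32 of 3953 genes were called in fibroblast-like cells (24 higher, 8 lower) and 66 of 4161 in macrophage-like cells (48 higher, 18 lower). These values compare partly different clusters. Fibroblast cluster 16 held 40.9% and 50.3% of its class in the knockout sections and 0.447% in the control, and macrophage cluster 13 held 22.8% and 34.0% of its class against 0.515%. Tnc, Grem1 and Saa1 are among the 10 leading genes of fibroblast cluster 16, which made up 7.72% and 8.37% of kept cells against 0.0735%, so transcripts of neighbouring fibroblasts were not excluded in macrophage-like cells. Of 33 cytokines and chemokines in fibroblast-like cells 3 rose (13 adjusted over the list alone), with Cxcl1 at 5.58 and Il6 at 6.26, camera adjusted p = 3.29e-12, and adjusted p = 0.133 with an estimated correlation. Of 37 in macrophage-like cells 4 rose (12 higher and 1 lower adjusted over the list alone), with Osm at 3.68 and Ccl2 at 1.46, camera adjusted p = 1.55e-08, and adjusted p = 0.457 with an estimated correlation. Without Nedd8 Nrf2 knockout 1 or knockout 2, 0 genes were called in fibroblast-like cells, and 20 and 11 in macrophage-like cells, where Cd36, Slc40a1, Ppl, Gpc3 and Nrg1 were lost both times. Clustering on all panel genes lost Saa1, Cd36, Ppl and Slc40a1 in macrophage-like cells, and library-size scaling lost the last 3 of these. Only the groups compared lost Saa1 and Tnc there, Xist as a covariate Cd36 and Slc40a1, resolution 2 Ppl and Slc40a1, and the floor of 50 transcripts Ppl. In fibroblast-like cells Cxcl5 and Saa1 were lost with no filter on low counts and with only the groups compared, and Gpm6a with slide as a block. Xist as a covariate lost Adcy1, Cxcl5, Gpm6a and Saa1 there. Without the section labelled control skin 1 the fibroblast-like count was 12, with Adcy1, Cemip, Cxcl5, Gpm6a and Saa1 lost, and without the section labelled Nedd8 knockout wound 2 the counts were 195 and 180.

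Over whole sections of Nedd8 Nrf2 knockout skin, 133 of 5067 genes were called by edgeR with Benjamini-Hochberg adjustment, 73 higher and 60 lower. Sprr2f (7.11), Cxcl5 (6.46), Il24 (6.44) and Cemip (6.43) rose, and Il22ra2 (-4.87), Clca3a2 (-4.85), the ligand Wnt3 (-4.00) and the melanocortin receptor Mc5r (-3.70) fell. Of 28 stress and wound genes 7 rose (21 adjusted over the list alone), with camera adjusted p = 1.5e-22, and adjusted p = 0.0592 with an estimated correlation. Of 43 cytokines and chemokines 9 rose (15 adjusted over the list alone), including Ccl12 (2.80), Osm (3.78) and Il6 (4.84), with camera adjusted p = 6.24e-15, and adjusted p = 0.138 with an estimated correlation. Scaling by library size alone gave 200 calls, 86 higher and 114 lower. The whole-section count was 0 without Nedd8 Nrf2 knockout 1, 14 without knockout 2, 18 without the section labelled control skin 1 and 475 without the section labelled Nedd8 knockout wound 2. Both without knockout 2 and without control skin 1, Clca3a2 and Il24 were the only named genes left. Slide as a block lost Il22ra2 and Sprr2f, the floor of 50 transcripts lost Sprr2f, Xist as a covariate lost Mc5r, and leaving out the sections labelled control skin 1 and Nedd8 knockout wound 2 together lost Cemip, Il22ra2 and Mc5r.

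Cell classes also differed in share. Neutrophil-like cells made up 2.49% and 4.17% of kept cells in Nedd8 Nrf2 knockout skin and 4.87% and 3.17% in the sections labelled Nedd8 knockout wound, against 0.447% in the Nrf2-null control and 0.242% in the control wound. The control values depend on the clustering, with 0.147% and 0.136% in the Nrf2-null control and 0.146% and 0.539% in the control wound at Leiden resolution 2 and on all panel genes. The 4 sections labelled as Nedd8 knockouts then had between 2.11% and 6.75%. Among cells with at least 50 transcripts the share was 1.44% and 3.07% in Nedd8 Nrf2 knockout skin, 2.18% and 2.69% in the sections labelled Nedd8 knockout wound, 0.245% in the Nrf2-null control and 0.0806% in the control wound. Macrophage-like cells made up 35.1% and 30.5% in Nedd8 Nrf2 knockout skin against 12.5% in the Nrf2-null control, but 23.2% and 29.2% in control skin. Sebocyte-like cells, which produce sebum, made up 0.832% and 1.19% against 3.91%. Shares were not tested across sections in the comparisons that have a single control section. Between Sumo2 knockout and control skin, none of 16 classes could be called, since the smallest p that the two-sided exact permutation test allows is 0.33, and the Benjamini-Hochberg adjusted p was 1 for each.

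**Figure D3:**
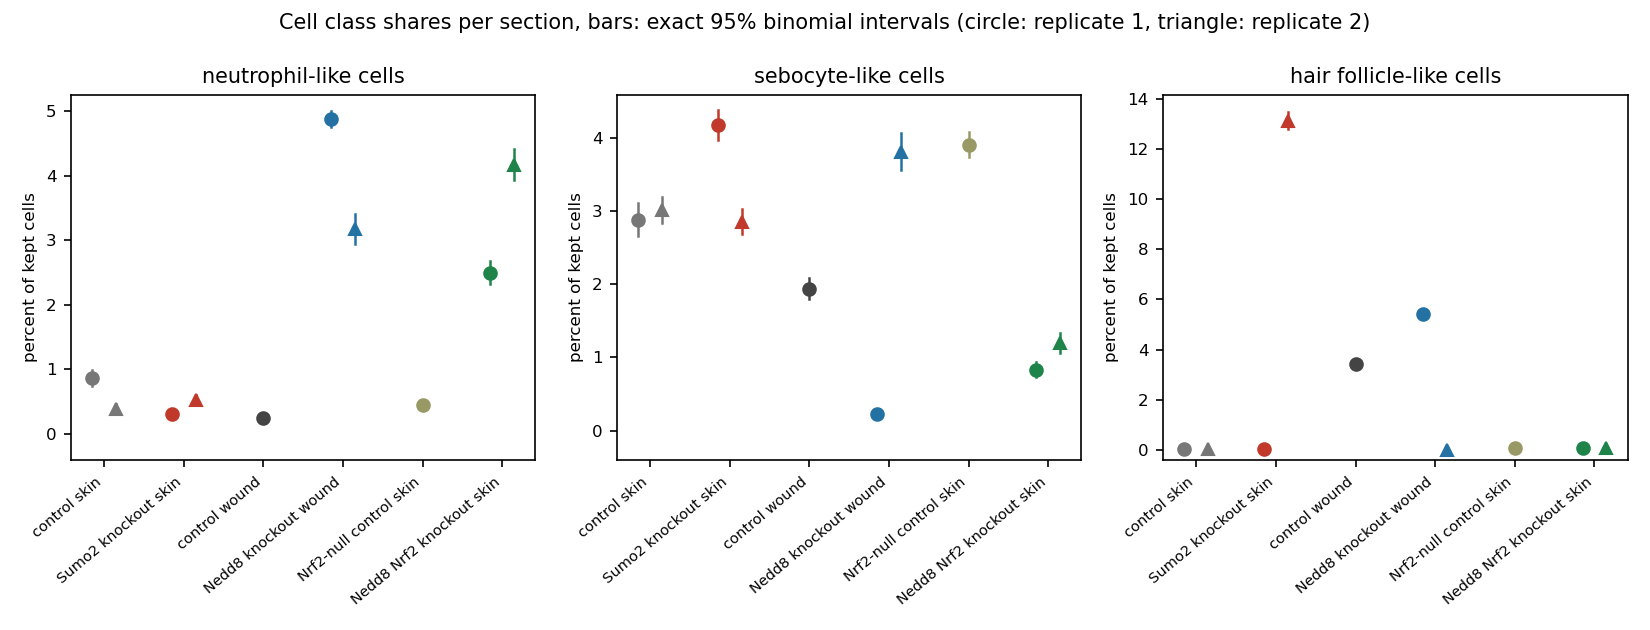
Percent of kept cells in the neutrophil-like, sebocyte-like and hair follicle-like classes of each section, with exact 95% binomial intervals that cover counting error only. Neutrophil-like cells were between 2.49% and 4.87% in the 4 sections labelled as Nedd8 knockouts and between 0.242% and 0.861% in the other 6.

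Nedd8 knockout wounds were set against the control wound to ask how Nedd8 loss changes repair. Direction here rests on labels in doubt, since the section labelled wound 1 kept Nedd8 at 617 CPM and the section labelled wound 2 held few wound-type fibroblasts (3.17% of kept cells, against 31.4% and 30.7% in wound 1 and the control wound). In keratinocyte-like cells the glutamate transporter Slc1a1 rose, at 253 and 202 CPM against 7.1 CPM (log2 change 4.99, SE 0.62). Acetylcholinesterase Ache (-3.84), the procollagen protease Adamts14 (-3.36) and smooth muscle actin Acta2 (-2.29) fell, with Acta2 at 63.6 and 81.2 CPM against 354 CPM. These 4 of 3803 genes were called by the edgeR quasi-likelihood test, each with a Benjamini-Hochberg adjusted p = 0.0404, while 767 had an unadjusted p under 0.05 and DESeq2 called 218. Acta2 in the same single control wound was also higher than in control skin, so a high value in that section could give both shifts. In keratinocyte-like cells of Nedd8 Nrf2 knockout skin Acta2 rose rather than fell. Transcripts of neighbouring cells were not excluded for Acta2. Clusters 11 and 20 held 35.1% and 84.1% of the keratinocyte-like cells of wounds 1 and 2 and 5.17% of those of the control wound. Without the section labelled wound 1, 554 genes were called, without the section labelled wound 2, 107, and without control skin 1, only Slc1a1. Wound 2 differs from the control wound in slide and in Xist (478 against 0.395 CPM). The calls made without wound 1 are therefore confounded with slide and sex. The Nedd8 difference of -2.08 shares that design. Yet keratinocyte-like Nedd8 was 857.5 CPM in control skin 2 and 821 CPM in the Nrf2-null control, both on the second slide. The Nrf2-null control also had high Xist (536 CPM). In wound 2, Nedd8 was 737 CPM in fibroblast-like and 1020 CPM in macrophage-like cells, against 587 and 846 CPM in the control wound. These values argue against slide or sex as the whole cause of the low Nedd8. None of the 4 was called at Leiden resolution 2, with only the groups compared, or with the unnamed follicle-type clusters pooled in, and Adamts14 and Slc1a1 were lost with slide as a block.

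By list, camera at its preset correlation placed cell cycle genes upward in keratinocyte-like cells of the sections labelled Nedd8 knockout wound, with none of 44 called over all genes and 15 higher when adjusted over the list alone. Ccna2 was at 2.07, the replication factor Mcm2 at 1.77 and Uhrf1 at 2.76, with camera adjusted p = 2.47e-11, and adjusted p = 0.646 with an estimated correlation. The same single control wound also had cell cycle genes shifted downward against control skin, so low values in that section could give both shifts. Keratinocyte-like cells had a median of 193 transcripts in the control wound against 471 and 622 in wounds 1 and 2. Stress and wound genes (Tgfa at 1.93, Il24 at 3.36, 1 higher adjusted over the list alone, camera adjusted p = 7.85e-06) and hypoxia and HIF targets (Hk2 at 1.39, Vegfa at 1.14, none adjusted over the list alone, camera adjusted p = 0.000153) shifted upward, with adjusted p = 0.502 with an estimated correlation for both. Camera also called heat shock and proteasome genes (adjusted p = 0.000946, 3 higher adjusted over the list alone), interferon response genes and unfolded protein genes (both 0.0197) and cytokines (0.0352, with Cxcl1 at 3.97 and 4 higher adjusted over the list alone) upward, all with adjusted p = 0.646 with an estimated correlation. Basal keratinocyte genes shifted downward (camera adjusted p = 0.0197, 5 lower adjusted over the list alone, Sox6 at -2.81), with adjusted p = 0.646 with an estimated correlation, as did scar matrix genes (0.00721, 2 lower adjusted over the list alone), with adjusted p = 0.502 with an estimated correlation. The median and mean of the epithelial-mesenchymal list differ in sign (0.18 and -0.04).

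In macrophage-like cells of the sections labelled Nedd8 knockout wound, the matricellular gene Thbs1 rose (3.18, SE 0.35, edgeR adjusted p = 0.00904), and the cell cycle inhibitor Cdkn1c (-3.19) and lipoprotein lipase Lpl (-2.18) fell. These 3 of 4161 genes were called, against 457 at an unadjusted p under 0.05 and 46 by DESeq2. Thbs1 alone was called with library-size scaling, none of the 3 with clustering on all panel genes, and Lpl was lost at Leiden resolution 2. Cluster 1 held 87.7% of the class in the control wound and 86.1% in the section labelled wound 1 but 19.6% in wound 2, where cluster 13 held 26.4% against 0.376% in the control wound. Median depth of the class differed too, at 55 transcripts in the control wound, 68 in wound 1 and 281 in wound 2. In fibroblast-like cells edgeR called 0 of 3953 genes, with 402 at an unadjusted p under 0.05 and 47 called by DESeq2. The smallest p belonged to Gdf10 (-2.57), the hypoxia factor Epas1 (3.24), Irs1 (-2.0), Cxcl1 (3.31) and Gpc6 (-1.81). Camera called cytokines (adjusted p = 3.23e-08, 3 higher adjusted over the list alone) and NF-kB genes (5.24e-08, 6 higher adjusted over the list alone) upward in these fibroblast-like cells, with adjusted p = 0.319 with an estimated correlation for both. The clusters of this class differed too, since cluster 0 held 91.5%, 90.7% and 19.6% of it in the control wound and the sections labelled wound 1 and wound 2, and cluster 16 held 0.107%, 1.5% and 37.4%. Over whole sections edgeR called 0 of 5067 genes, with 405 at an unadjusted p under 0.05 and 61 called by DESeq2. The values were 3.26 for Slc1a1, 2.11 for the glycerol kinase Gk, 1.76 for Slc6a14, -1.31 for Irs1 and 2.06 for the formyl peptide receptor Fpr2. Without the section labelled wound 1 the counts were 114 in whole sections, 115 in fibroblast-like and 81 in macrophage-like cells. When the section labelled wound 2 was left out they were 12, 16 and 26, and without control skin 1 the macrophage-like count was 10.

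Sumo2 knockout skin was set against control skin to ask what epidermal Sumo2 loss does. The direction rests partly on the section labelled control skin 1, whose keratinocyte-like cells had as little Sumo2 as the knockout sections. No single gene was called by edgeR in any compartment. In keratinocyte-like cells 0 of 3803 genes were called, with 222 at an unadjusted p under 0.05 and 5 called by DESeq2. The smallest p belonged to the EGF receptor ligand Ereg, at 609 and 1085 CPM against 229.8 and 261 CPM (log2 difference 1.79, SE 0.29, edgeR adjusted p = 0.809), and to Gem (-1.46), Fgfbp3 (1.52), Fhl2 (2.42) and the glycogenin Gyg (-2.28). Whole sections gave 0 of 5067 genes by edgeR (397 at an unadjusted p under 0.05, 34 by DESeq2), with Cpa4 at 1.47, Ereg at 1.84, the macrophage gene Aif1 at -1.39, Cd300ld at -1.52 and Plk3 at 1.35. Fibroblast-like cells gave 0 of 3953 by edgeR (106 at an unadjusted p under 0.05, 0 by DESeq2), with Clu at 0.83, Peg3 at 1.5, Cyb561 at -1.11 and Cpa3 at 1.94. Macrophage-like cells gave 0 of 4161 by edgeR (102 at an unadjusted p under 0.05, 0 by DESeq2), with Gjb2 at 2.52, Slc9a3r1 at -1.01, Trdn at 1.29, Ffar2 at 2.0 and F2r at 2.94. With the section labelled control skin 1 and the section labelled Nedd8 knockout wound 2 both left out, 50 genes were called in keratinocyte-like cells (22 higher, 28 lower) and 50 in macrophage-like cells, and 0 in the others. These calls are confounded with slide, since the remaining control lay on the second slide and both Sumo2 knockout sections on the first. The whole-section count was 2 without Sumo2 knockout 1.

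Several lists shifted as groups in keratinocyte-like cells of Sumo2 knockout skin, although no member passed the test over all genes. The 44 cell cycle genes had a median log2 difference of -0.78, with the mitotic cyclin Ccnb1 at -1.20, the kinetochore gene Cenpf at -0.95 and the checkpoint kinase Bub1 at -1.38 (camera adjusted p = 4.15e-17, 0 adjusted over the list alone), and adjusted p = 0.853 with an estimated correlation. Keratinocyte differentiation genes shifted upward, with Prdm1 at 0.91, filaggrin Flg at 1.86 and Ovol1 at 0.61 (camera adjusted p = 7.44e-06, 0 adjusted over the list alone), and adjusted p = 0.650 with an estimated correlation. Interferon response genes shifted upward (camera adjusted p = 0.0244, Ifit1 at 3.30), and NF-kB genes and DNA damage genes downward (camera adjusted p = 0.0216 for both, Tnip3 at -3.15), with adjusted p = 0.853 with an estimated correlation for all. When adjusted over the list alone, 1 NF-kB gene was lower and 1 stress and wound gene was higher, and medians and means differ in sign for the cell death and scar matrix lists. Over whole sections differentiation genes shifted upward (camera adjusted p = 3.70e-12, 5 higher adjusted over the list alone) and bystander genes downward (6.28e-05), with adjusted p = 0.0832 with an estimated correlation for both. Some immune cell shares moved with the bystander genes, at a mean of 15.1% against 26.2% for macrophage-like and 5.40% against 8.46% for dendritic or Langerhans-like cells. Others did not, at 0.746% against 0.407% for mast-like and 2.17% against 2.22% for T or NK-like cells. Neutrophil-like cells averaged 0.414% against 0.628%, and melanocyte-like cells 0.498% against 0.102%. Epithelial shares differed as well, at a mean of 13.04% against 11.18% for keratinocyte-like cells, and hair follicle-like cells made up 13.1% of Sumo2 knockout 2 but 0.0209% of Sumo2 knockout 1.

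The control wound was set against control skin, which includes the section labelled control skin 1 with its low Sumo2, to ask what differs in wounds without a knockout. The 2 groups also differ in the floxed gene named in their genotype labels (Nedd8 and Sumo2) and in days of tamoxifen (3 and 5). Control skin 2 lay on the other slide. In keratinocyte-like cells Acta2 rose, at 354 CPM against 16.7 and 17.3 CPM (4.37, SE 0.29, edgeR adjusted p = 0.000815), and it was the only gene of 3803 called, while 589 had an unadjusted p under 0.05 and DESeq2 called 67. The scar matrix list shifted upward (camera adjusted p = 2.32e-07, 2 higher adjusted over the list alone), with Runx1 at 2.60 and adjusted p = 0.104 with an estimated correlation. Fibroblast-like cells made up 33.5% of the control wound against 15.7% and 16.2% of control skin, and wound-type cluster 0 30.7% against 3.66% and 3.21%, so transcripts of neighbouring fibroblasts were not excluded. Cell cycle genes shifted downward, with Cenpf at -2.22 (camera adjusted p = 7.35e-13, 6 lower adjusted over the list alone), and stress and wound genes upward, with Krt6a at 2.46 (camera adjusted p = 2.76e-05), with adjusted p = 0.800 with an estimated correlation for both. The keratinocyte-like values compare partly different clusters. Cluster 9 held 1185 of 3807 such cells in the control wound, against 1236 of 2266 and 2186 of 4310 in control skin. Cluster 10 held 2074 against 658 and 1393. Over whole sections edgeR called 0 genes (546 at an unadjusted p under 0.05, 56 by DESeq2), with Timp1 at 2.71, Col8a1 at 2.89, Cdh4 at -2.62, the leukocyte gene Ptprc at -1.82 and Glis3 at 2.23. Without the section labelled Nedd8 knockout wound 2 the counts were 98 in keratinocyte-like cells and 38 in whole sections.

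Nrf2-null control skin was set against the same control skin, again including the section labelled control skin 1, to show the background on which Nedd8 was deleted. The Nrf2-null control had 536 CPM of Xist and the control skin sections 0.261 and 4.02 CPM, so sex and Nrf2 loss cannot be separated here. Nfe2l2 itself had 1 count against 1313 in keratinocyte-like cells, a ratio of 1418 with a counting interval of 254 to 56040 (edgeR adjusted p = 0.000347), and it was the only gene of 3803 called, while 56 had an unadjusted p under 0.05 and DESeq2 called 2. Camera called lists of differentiation (adjusted p = 0.0145, Flg at -2.23), hypoxia (0.0145, Hk2 at -0.93), stress and wound (0.0176, Krt6a at -2.20), scar matrix (0.0176), interferon (0.0351) and p53 genes (0.0418) lower, and cell cycle (0.0272) and basal keratinocyte genes (0.0418) higher. Each of these had an adjusted p between 0.720 and 0.736 with an estimated correlation.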

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

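The tests of the low Sumo2 section, of the wound section, of sex and of Nedd8 loss in this part were chosen only after the results were seen, and the test of cluster mix was chosen before.

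The Sumo2 comparison differed from the Nedd8 Nrf2 comparison for 171 of 3803 genes in keratinocyte-like cells, 105 with a higher and 66 with a lower Sumo2 effect. The edgeR quasi-likelihood test was made on the difference itself, with Benjamini-Hochberg adjustment. Alone, the Sumo2 comparison called 0 genes in this class, and Sumo2 itself was not called, so an effect of Sumo2 loss was not shown. Among single genes with a higher Sumo2 effect, the log2 difference was 6.15 for Sema3d, 5.94 for Adamts14, 5.48 for Sox6 and 5.44 for Clca3a2. Among those with a lower one it was -9.45 for Il24, -7.86 for Cntn2, -6.03 for Krt6a and -5.74 for Nrg1. For Sema3d, Adamts14, Sox6, Clca3a2 and Cntn2 these differences were close to the Nedd8 Nrf2 changes with the sign turned. The same test called 19 higher and 42 lower in whole sections, 5 and 12 in macrophage-like cells and 0 in fibroblast-like cells. Krt6a was lost with slide as a block and with Xist as a covariate, and Sema3d with no filter on low counts and with pooled follicle-type clusters. The Sumo2 side rests partly on the section labelled control skin 1, and the designs also differ in background and slide. Single sections carried much of the count, which was 4 without Sumo2 knockout 1, 71 without Sumo2 knockout 2, 43 without the section labelled control skin 1, 5 without control skin 2, 3 without Nedd8 Nrf2 knockout 1, 41 without Nedd8 Nrf2 knockout 2 and 650 without the section labelled Nedd8 knockout wound 2. Of these 8 genes Adamts14 alone remained called without Sumo2 knockout 1, without control skin 2 or without Nedd8 Nrf2 knockout 1.

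Keratinocyte-like cells of the section labelled control skin 1 had 158 CPM of Sumo2 against 1168 CPM in control skin 2. A loss of Sumo2 signal over that whole section is argued against, since the median ratio of the section labelled control skin 1 to control skin 2 over the non-epithelial classes was 1.29. Weaker detection on the first slide is argued against too, since the control wound and the section labelled Nedd8 knockout wound 1 on that slide kept at least 0.587 of the level of control skin 2. Its keratinocyte-like Sumo2 was 1.07 times the mean of the Sumo2 knockout sections, or 158 against a mean of 182 CPM with TMM scaling, which is consistent with recombination of Sumo2 there, by a wrong label or without intent. Which of these applies stays open, and no partner out of place was seen among the Sumo2 knockout sections. The 3 ratios in this paragraph are of CPM without TMM scaling.

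The section labelled Nedd8 knockout wound 2 held few wound-type fibroblasts, 3.17% of its kept cells. That lies inside the range of 2.43% to 9.21% in the 7 unwounded sections, which may reflect a section without wound bed, by a wrong label or by where it was taken. A loss of such fibroblasts after Nedd8 deletion is not settled. The section labelled Nedd8 knockout wound 1 had 1.03 times the share of the control wound. However, wound 1 also kept most of its Nedd8 over the keratinocyte-like class, though less in some clusters. Other values also set wound 2 apart from the other wounds. Macrophage cluster 1 held 3.20% of its kept cells against 16.0% in the control wound and 18.7% in wound 1, and hair follicle-like cells 0.0134% against 3.44% and 5.41%. Its log2 CPM over the whole section correlated at 0.977 and 0.981 with Nedd8 Nrf2 knockout skin, 0.9495 with wound 1 and 0.939 with the control wound, but unlike Nrf2-null skin it kept Nfe2l2. For wound 2 the 2 explanations cannot be told apart without a wound that lacks Nedd8 and surely holds wound bed.

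Of the 655 genes called between Nedd8 Nrf2 knockout skin and its control in keratinocyte-like cells, a sex difference as the whole cause is argued against, because 99.4% (651) kept their sign and at least 0.5 of the change in knockout 2 against the control, both of which had high Xist (471 and 536 CPM). Knockout 2 is part of the fit, so this share is partly built in. A different mix of keratinocyte clusters is left open. Within 5 clusters, which are not replicates, the median change averaged 0.533 (SD 0.184) of that of the class. The demand that a value lie beyond this spread was set after it was seen. This ratio cannot decide, since clusters 11 and 20 held 45 and 60 control cells and clusters 9 and 10 held 113 and 194 knockout cells. A small count added before taking logs pulls changes at few counts toward 0. The clusters were also built from expression, which the knockout itself may have changed. Nedd8 loss is left open as well. In the sections labelled Nedd8 knockout wound against the control wound, 89.6% (587) had the same sign, with 84.4% in wound 1 and 88.7% in wound 2. The Sumo2 comparison gave 61.7%. Wound 1 reached its share while keeping 617 CPM of Nedd8 over the class against 672 CPM in the control wound. In cluster 11, Nedd8 without TMM scaling was 235 CPM in wound 1 against 506 CPM (16 counts) in the control wound. In cluster 24 it was 113 against 225 CPM, and in cluster 10 it was 522 against 603 CPM. In clusters 9 and 20 it was not lower, at 1065 against 1053 CPM and 1277 against 1095 CPM (19 counts). Deletion in only part of the wound 1 cells was not tested. Clusters 11 and 20 held 35.1% and 84.1% of the class in wounds 1 and 2 against 5.17% in the control wound. These shares therefore cannot separate Nedd8 loss from cluster mix, and the same-sign share over all genes was not computed. All 3 skin sections compared lay on the second slide, so a difference between slides does not separate them. The single control section and the doubt about both wound labels stay open.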

How the results depend on the processing

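The alternatives that left out the sections labelled control skin 1 and Nedd8 knockout wound 2 together, left out one of them from comparisons it is not part of, added Xist as a covariate or pooled the unnamed follicle-type clusters were chosen after seeing the data, and the others before. Among counts of called genes, 138 values under alternatives stayed within 1.5 times the main count and 93 did not. Named genes kept their side of the threshold in 1186 cases, lost the call in 163 and gained it in 53. None of the called values reversed, and direction was not compared where a gene was called in neither fit. Class shares moved beyond their spread in 38 of their alternatives and stayed within it in 34. The cause was not tested unless stated. Other splits of the samples were not counted for the gene tests, since no group held more than 2 sections.

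In keratinocyte-like cells DESeq2 called 5 genes for Sumo2, 218 for the Nedd8 wounds, 67 for control wound against skin, 2 for Nrf2-null against control skin and 414 for the difference between the Sumo2 and Nedd8 effects. In whole sections it called 34 for Sumo2, 61 for the Nedd8 wounds, 434 for Nedd8 Nrf2 and 56 for control wound against skin. It called 47 and 162 genes in fibroblast-like cells and 46 and 112 in macrophage-like cells for the Nedd8 wounds and Nedd8 Nrf2. With only the groups compared, the counts in keratinocyte-like cells were 0 for the Nedd8 wounds, 2026 for Nedd8 Nrf2, 4 for control wound against skin, 3 for Nrf2-null against control skin and 655 for the difference. They were 1507 and 600 in whole sections for Nedd8 Nrf2 and for control wound against skin, 671 in fibroblast-like cells for Nedd8 Nrf2, and 71 and 573 in macrophage-like cells for the Nedd8 wounds and Nedd8 Nrf2, and 2 lists were called for Sumo2 in keratinocyte-like cells.

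With the sections labelled control skin 1 and Nedd8 knockout wound 2 left out, keratinocyte-like cells gave 50 genes for Sumo2, 163 for the Nedd8 wounds, 1398 for Nedd8 Nrf2, 135 for control wound against skin, 2 for Nrf2-null against control skin and 749 for the difference. The Nedd8 wound counts then rest on wound 1 alone, which kept most of its Nedd8 over the keratinocyte-like class. The Sumo2 counts are confounded with slide. The Sumo2 gene itself was then called at -2.67 (edgeR adjusted p = 0.0150), fibroblast-like cells gave 3 and 203 genes for the Nedd8 wounds and Nedd8 Nrf2, macrophage-like cells gave 50, 148 and 350 for Sumo2, the Nedd8 wounds and Nedd8 Nrf2, and 5 lists were called in whole sections for the Nedd8 wounds. With no filter on low counts the Nedd8 wounds gave 41, 4 and 14 genes in keratinocyte-like, fibroblast-like and macrophage-like cells, Nedd8 Nrf2 gave 60 in fibroblast-like cells and 8 lists in keratinocyte-like cells, control wound against skin gave 10, and Nedd8 stood at -2.30 in Nedd8 Nrf2 keratinocyte-like cells without a call. Library-size scaling moved the median of all genes by over 0.1 for Sumo2 (-0.24, 0.16 and 0.12 in keratinocyte-like, fibroblast-like and macrophage-like cells), for Nedd8 Nrf2 (-0.41 in keratinocyte-like cells and -0.16 in whole sections), for control wound against skin (-0.25 and 0.15) and for the difference (0.21). It gave 17 and 1 genes for the Nedd8 wounds in keratinocyte-like and macrophage-like cells, 200 and 36 for Nedd8 Nrf2 in whole sections and macrophage-like cells, and 2 for control wound against skin. Slide as a block gave 2 and 10 genes for the Nedd8 wounds in fibroblast-like and macrophage-like cells, 137 for Nedd8 Nrf2 in macrophage-like cells and 2 for control wound against skin in keratinocyte-like cells. Xist as a covariate gave 10 and 5 genes for the Nedd8 wounds in keratinocyte-like and macrophage-like cells, 67 for Nedd8 Nrf2 in whole sections and 6 for control wound against skin. The first slide alone gave 3 and 7 genes for Sumo2 in keratinocyte-like and macrophage-like cells. Leiden resolution 2 and the pooled follicle-type clusters each gave 0 genes for the Nedd8 wounds in keratinocyte-like cells, and pooling gave 63 for the difference. Clustering on all panel genes gave 0 and 23 genes in macrophage-like cells for the Nedd8 wounds and Nedd8 Nrf2. An estimated correlation left 0 lists in all 6 sets of list tests.

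Leaving out 1 replicate at a time, with a lone section assumed to vary like the other groups, gave 113 to 1226 genes for Nedd8 Nrf2 in keratinocyte-like cells, 0 to 475 in whole sections, 0 to 195 in fibroblast-like and 11 to 180 in macrophage-like cells. For the Nedd8 wounds the ranges were 1 to 554, 0 to 114, 0 to 115 and 10 to 81. They were 3 to 650 for the difference between effects, 0 to 2 for Sumo2 in whole sections, and 1 to 98 and 0 to 38 for control wound against skin in keratinocyte-like cells and whole sections. Lists called ranged from 4 to 8 for Nedd8 Nrf2 and 3 to 5 for Sumo2 in keratinocyte-like cells, and from 5 to 8 for the Nedd8 wounds in whole sections. The Nedd8 log2 difference ranged from -2.27 to -2.21 in Nedd8 Nrf2 and from -2.08 to -0.16 in the wounds.

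The replicate numbers share only a number, since deviations of same-numbered sections in the Sumo2 comparison correlated at -0.12 in keratinocyte-like cells, -0.07 in whole sections, -0.09 in fibroblast-like and -0.03 in macrophage-like cells. With the replicate block, 0 genes were called in each of these 4 compartments and 2 lists in keratinocyte-like cells. With the numbers crossed in keratinocyte-like cells, 0 genes were called.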

Other observations

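The test of NRF2 targets in this part was chosen only after the values were seen, and the genes and classes described here were picked after their values were seen.

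A pair of genes followed the Nedd8 knockout labels in classes that K14-Cre does not target, where transcripts of neighbouring cells were not excluded. Epas1, which encodes the hypoxia-inducible factor HIF-2 alpha, stood in fibroblast-like cells at 1988 and 1646 CPM in the sections labelled Nedd8 knockout wound and at 2389.7 and 2390 CPM in Nedd8 Nrf2 knockout skin, and between 126 and 296 CPM in the other 6 sections. It was called in Nedd8 Nrf2 knockout skin (3.99, SE 0.45, edgeR with Benjamini-Hochberg, adjusted p = 0.0254) and not in the wounds (3.24, edgeR adjusted p = 0.115). The call in skin was lost when either Nedd8 Nrf2 knockout section was left out. In macrophage-like cells Epas1 was between 481 and 668 CPM in the 4 sections labelled as Nedd8 knockouts and between 80.4 and 177 CPM in the others. Thbs1, the matricellular protein thrombospondin, was between 1042 and 1214 CPM in macrophage-like cells of those 4 sections and between 102 and 161 CPM in the other 6, and was called in both comparisons (3.38 and 3.18 on the log2 scale, edgeR adjusted p = 0.00332 and 0.00904).

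Shares of 2 classes of skin appendages differed widely between sections. Hair follicle-like cells made up 13.1% of kept cells in Sumo2 knockout 2, 5.41% in the section labelled Nedd8 knockout wound 1 and 3.44% in the control wound, and at most 0.0924% in each of the other 7 sections. Sebocyte-like cells made up 0.224% in the section labelled Nedd8 knockout wound 1, 3.81% in wound 2 and 1.93% in the control wound. Between Sumo2 knockout and control skin the exact permutation test gave p = 1 for both classes, and the wounds were not tested.

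Nqo1, an NRF2 target, stood at 119 and 1118 CPM in keratinocyte-like cells of the sections labelled Nedd8 knockout wound, against 35.5 CPM in the control wound. It was 24.7 CPM in both Nedd8 Nrf2 knockout sections, against 16.2 CPM in the Nrf2-null control. A hypothesis is that NRF2 targets may rise after Nedd8 loss where Nrf2 is intact. The wound effect minus the skin effect was higher for 9 of 12 NRF2 targets, with Gsta1 at 7.09 and Nqo1 at 3.51, and camera at the estimated correlation gave p = 0.718, so the question stays open. Most of the difference came from the section labelled wound 2, where Gsta1 was 1506 CPM against 61.9 CPM in wound 1, and wound and skin differ in more than Nrf2.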
